A study of Mus musculus with 9 samples.

How the data were processed

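Messenger RNA was measured in 9 libraries of mouse oocytes at metaphase II, 3 from a young group, 3 from an aged group and 3 from a group supplemented with nicotinamide mononucleotide (NMN). Per the labels' protocols, the libraries were made by Smart-seq2, in which RNA is reverse transcribed from an oligo(dT) primer into full-length cDNA and then amplified. Sequencing libraries were built by the DNBseq route. The sample descriptions name an MGISEQ-2000 instrument, whereas the design text of the series names an Illumina platform. Groups and replicate numbers were taken from the sample titles, and each column of the deposited table was matched to a sample through the sample description.

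The authors deposited 1 table of 22526 genes. Its name calls it a raw count matrix, but the deposited values are FPKM, read fragments scaled to transcript length and to the size of the library. They are fractional and sum to between 300369 and 329359 per library. Per the submitters' processing notes, Bowtie2 2.2.5 and RSEM were used with the mouse build mm9. The role of each tool, the gene annotation and any filter on genes were not given in the sources used here. Of the gene identifiers, 22487 (99.83%) were matched to a symbol in the GENCODE M21 annotation. That annotation is on a later build than the mm9 named in those notes. The annotation behind the deposited identifiers is not stated. GENCODE M21 therefore served only for gene names, transcript lengths and the order of genes along chromosomes, and no coordinates are given. No column of the table belonged to other samples.

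Depth was estimated from the low values. For 2659 genes with 1 annotated transcript of over 1500 nt, value times length fell on whole multiples of 1 step per library, within 0.02 reads, for 96.2 to 97.8% of the values below 20 reads. The steps gave 16.28 M to 19.25 M reads per library (M, mega). A gene of 2 kb with 3 reads would have 0.0779 to 0.0921 FPKM, which was taken as the detection floor and covers counting error only. The read counts themselves were not recovered for genes with several transcripts. Same-group libraries differed by far more than sampling noise, with chi-square values of 19.47 to 140 per degree of freedom, so no library was counted as a repeat of another.

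The tests had been planned for counts, with a quasi-likelihood count model. Because the values were FPKM, limma was used on log2(FPKM + 1) in its place. FPKM were divided by trimmed-mean factors (30% trimmed by ratio, 5% by level). Genes with at least 1 FPKM in at least 3 libraries were kept, which left 9168. All 9 libraries entered 1 fit of group means without covariates, in limma 3.58.1 under R 4.3.3, with a variance trend and robust moderation. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p under 0.05 made a call. Replicate numbers are shared between the groups, and the labels tie them to no animal or day. Libraries with the same number were treated as pairs where all 3 correlations of their deviations from the group means were over 0.1. That was so for NMN and young libraries (0.497, 0.12 and 0.143), but not for aged and young (-0.338, -0.266 and 0.314) or NMN and aged (-0.372, -0.357 and 0.202). For NMN against young, the fit with the number as a block is therefore given where it changes a call. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Data were also simulated with independent noise per gene and 200 changed genes among the 9168. On them, the same steps recovered 40% (aged against young), 42% (NMN against aged) and 43% (NMN against young) of genes changed by 1 on the log2 scale. For changes of 2 the shares were 89%, 89% and 91%. Of the simulated calls, 6.52%, 5.07% and 4.29% were false.

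For 22 lists of pathway genes, limma's camera was run with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. It was repeated with a correlation estimated per list, and fry was run as another test. In 1 simulated set, drawn with independent noise per gene, a proteasome list shifted by 0.5 was recovered. The estimated correlation of the real list was 0.233, so this does not show recovery among correlated genes. Counts of list members that passed were made over all tested genes and over each list alone. Another 8 lists held markers of cell types, of handling and of early embryonic transcription. Their FPKM as deposited were summed per library and compared by a two-sided exact permutation test. With 3 libraries against 3, that test cannot give a p below 0.1.

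Genes were named by a fixed rule. Per comparison these were the 10 largest increases and the 10 largest decreases among called genes whose groups did not overlap, with a mean of at least 10 FPKM in the higher group, leaving out predicted or unnamed genes. Up to 4 members per pathway list with the smallest p, a fixed set of oocyte, antioxidant and NAD genes, and the 10 genes most firmly called in opposite directions in aged against young and in NMN against aged were added. Groups, comparisons, lists, naming rule and the first set of other settings were fixed before the data were examined. The naming rule and the gene filter had been written for counts, and their cutoffs in FPKM took the place of those planned. Aged against young and NMN against aged both use the aged libraries, so chance alone gives opposite moves. Unchanged groups were therefore simulated 100 times with independent noise per gene. After the data were seen, 100 simulations that kept the correlation between genes were added, with each library drawn as a random mixture of the 9 libraries' deviations from their group means. The first simulations kept the spread of each group, whereas the added ones gave every group the same pooled spread. Both sets of simulations drew the libraries independently of each other, so neither kept pairs by replicate number.

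The other settings fixed at that time were median-ratio factors, values as deposited, no filter, a minimum of 10 FPKM, library quality weights, only the libraries of the groups compared, each library left out in turn, a block for the replicate number and a minimum change of 1 on the log2 scale. Pseudocounts of 0.1 and 5, removal of each library's trend with transcript length, alone or with the block, and list tests without aged replicate 2 were added after the data were seen. A Wald count test and thinning to equal depth need counts and were not run. Genes with near-identical copies, such as Ppia, Calm2, Tcl1b5, Elobl, Tubb5, Cfl1, Rps2-ps6 and the predicted Gm genes, are uncertain, since reads may be shared among copies. Smart-seq2 does not mark the strand, so overlapping and antisense genes cannot be told apart.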

Results

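The transcriptomes of matured mouse oocytes were compared between a young group, an aged group and a group supplemented with NMN, a precursor of the coenzyme NAD, with 3 libraries each. The oocytes came from ICR mice, an outbred strain, and had reached metaphase II, the stage at which an ovulated egg awaits fertilisation. The series asks whether NMN counters the loss of oocyte quality with maternal age, and the labels of the NMN group do not give the age of its mice. Depth was 16.28 M to 19.25 M reads per library (M, mega) as estimated from the low values. The libraries listed 15762 to 16940 genes above 0 FPKM. The group means of this number, 16210 ± 404 in young, 16355 ± 582 in aged and 16070 ± 415 in NMN libraries (SD, n = 3), differed by less than the spread between libraries. The exact permutation p was 0.7 for aged against young and for NMN against aged, and 1 for NMN against young. Neither the number of oocytes in a library nor the mice behind it is given, so p-values measure only the spread between these libraries, which may be technical.

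The first principal component of the tested genes held 41.1% of the variance and separated aged replicate 2, at 57.02, from the other 8 libraries, which lay between -28.5 and 22.6 (NMN replicate 1). The second component held 19.3% and placed aged replicates 1 and 3, at -29.4 and -26.0, below the rest. Libraries of the same group correlated at 0.951 to 0.990 across genes, and genes are not independent replicates. Between libraries of different groups the range was similar, 0.937 to 0.985, so it does not set the groups apart. The oocyte markers, among them Gdf9, Bmp15 and the zona pellucida genes, summed to 7123 to 10220 FPKM in the 9 libraries. Ptx3, Inha, Fst and Tnfaip6, genes of the cumulus and granulosa cells that surround the oocyte, were at 6.37, 3.17, 2.31 and 1.08 FPKM in aged replicate 2 and listed at 0 in the other 8 libraries.

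**Figure D1:**
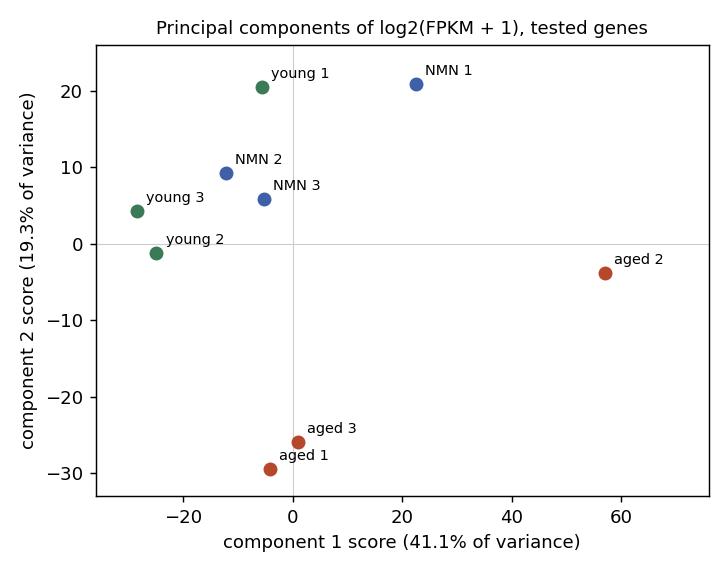
Scores of the 9 libraries on the first 2 principal components of log2(FPKM + 1) over the 9168 tested genes, 1 point per library. Aged replicate 2 lies at 57.02 on component 1, beyond NMN replicate 1 at 22.6.

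Aged oocytes held more mRNA of 125 genes than young oocytes, among them Tmed2, Ypel5, Pcp4l1, Gli3, Otx1 and Ube2t. Tmed2 (ENSMUSG00000029390), a cargo receptor of transport between endoplasmic reticulum and Golgi, rose from 11.1 ± 2.03 to 114 ± 34.8 FPKM (SD, n = 3 per group; log2 change 3.21 ± 0.26 SE, limma adjusted p = 0.000922). Ypel5 rose from 131 ± 12.4 to 468 ± 115 FPKM (log2 change 1.81 ± 0.25, adjusted p = 0.00952) and Pcp4l1 from 2.04 ± 0.91 to 31.0 ± 17.9 FPKM (3.22 ± 0.64, adjusted p = 0.0356). Gli3, a transcription factor of Hedgehog signalling, rose by 2.90 ± 0.61, the homeobox gene Otx1 by 1.83 ± 0.34, and Ube2t, a ubiquitin-conjugating enzyme of DNA crosslink repair, by 1.79 ± 0.36 (adjusted p from 0.0297 to 0.0440). Elobl, Ppia, Tcl1b5 and Calm2 rose by 2.09, 1.99, 1.86 and 1.77 (adjusted p from 0.0287 to 0.0450). These 4 have near-identical copies, and Elobl, Ppia and Tcl1b5 were more than 2 times as high in aged replicate 2 as in every other library, at 823, 117 and 1044 FPKM. Of these 10 calls only that of Tmed2 held without any 1 library, and the highest adjusted p was 0.189, for Elobl without young replicate 3.

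Other transcripts were lower in the aged group. Zfp961, a zinc finger gene, fell from 55.5 ± 12.4 to 12.5 ± 2.502 FPKM (log2 change -2.05 ± 0.22, limma adjusted p = 0.00361), and Vamp3 (ENSMUSG00000028955), a SNARE protein of vesicle fusion, from 28.1 ± 2.99 to 8.06 ± 1.11 FPKM (-1.69 ± 0.17, adjusted p = 0.00272). Mrpl9, a protein of the mitochondrial ribosome, fell by 1.69 on the log2 scale, and mt-Atp6, a mitochondrially encoded subunit of ATP synthase, fell by 1.59 (adjusted p = 0.00831 and 0.0108). Bst2, an interferon-induced antiviral membrane protein, fell by 1.59 and Cirbp, the cold-inducible RNA-binding protein, fell by 1.36 (adjusted p = 0.0484 and 0.0101). Serpinb3a, Rps2-ps6, Gtf2a1l, a germ-cell form of a basal transcription factor, and Vps37b, a subunit of the endosomal sorting machinery, fell by 2.46, 2.46, 1.51 and 1.42, with adjusted p from 0.0371 to 0.0478. The calls of Zfp961 and Vamp3 held without any 1 library, and the highest adjusted p of the other 8 was 0.180, for Bst2 without young replicate 3.

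In all, 201 of 9168 genes were called in aged against young oocytes, 125 higher and 76 lower (limma, adjusted p under 0.05), and 176 of them changed at least 2-fold. Other settings gave from 31 calls with no low-value filter to 881 with library quality weights. At an unadjusted p under 0.05 there were 1675 genes against 458.4 by chance. The 3 aged and 3 young libraries did not overlap for 2193 genes (23.9%), where chance gives 10%. Without young replicate 1, 2 or 3 the count was 40, 30 or 29, without aged replicate 3 it was 30 and without NMN replicate 3 it was 104. Without aged replicate 2 it was 211, 138 of them shared. Of the 45 calls named for this comparison, 16, 13 and 14 remained without young replicates 1 to 3, 31, 27 and 10 without aged replicates 1 to 3, and 34, 33 and 24 without NMN replicates 1 to 3. Without an aged replicate 4 of the 45 fell below the filter and were not tested. Of the 201 genes, 36 bear predicted or unnamed symbols.

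Mitochondrially encoded mRNAs and nuclear-encoded respiratory chain genes moved in opposite directions. All 10 tested mitochondrial mRNAs had a lower mean log2 value in the aged group, and the list fell with a median of -0.73 (camera adjusted p = 1.31e-05, and adjusted p = 0.803 with an estimated correlation). Of its members 2 fell, mt-Atp6 and mt-Nd1 (from 1268 ± 58.7 to 646 ± 120 FPKM, limma adjusted p = 0.0312), and 5 fell when adjusted over the list alone. The sum of these mRNAs was 5483 ± 441 FPKM in young and 3430 ± 1200 in aged libraries (SD, n = 3; exact permutation p = 0.1, the smallest possible). Aged replicate 2 stood apart in this list too, with 4813 FPKM against 2848 and 2630 in aged replicates 1 and 3, and without it the list's median was -1.12, 6 members fell and the adjusted p with an estimated correlation was 0.0556. Leaving out young replicate 1, 2 or 3, aged replicate 1 or 3 or NMN replicate 3 ended 1 or both member calls, with adjusted p up to 0.0739 for mt-Atp6 and 0.129 for mt-Nd1, both without young replicate 3. The mitochondrial rRNAs summed to 1809 ± 250 FPKM in young and 1767 ± 1200 in aged libraries (exact permutation p = 1), with 3155 FPKM in aged replicate 2.

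The nuclear-encoded respiratory chain and ATP synthase list rose, with a median of 0.65 over 44 tested members (camera adjusted p = 3.91e-06, and adjusted p = 0.803 with an estimated correlation). Of these 44 genes, 1 rose, Ndufc2 of complex I (2.25 ± 0.72 to 9.66 ± 3.99 FPKM, limma adjusted p = 0.0356, and up to 0.144 without young replicate 2), and 16 rose and 2 fell when adjusted over the list alone. The list of cytosolic ribosomal protein genes had a median of 0.79 over 33 members (camera adjusted p = 2.74e-05, and adjusted p = 0.803 with an estimated correlation), with 0 members past the limma test over all genes or adjusted over the list alone, and its summed FPKM was above the young libraries in aged replicate 2 alone of the aged group. The proteasome list had a median of 0.21 over 31 members (camera adjusted p = 0.0321, and adjusted p = 0.803 with an estimated correlation), and 3 members rose, Psma5 and Psmb2 of the catalytic core and Psmd9, an assembly chaperone, and 4 when adjusted over the list alone. Without 1 library Psmb2 had an adjusted p up to 0.179 and Psma5 up to 0.163, both without young replicate 3, and Psmd9 missed the threshold whichever was left out. The mitochondrial ribosomal list had a median of 0.30 over 53 members (camera adjusted p = 0.0364, and adjusted p = 0.803 with an estimated correlation), with 0 members that rose, and the single member past the test, over all genes and adjusted over the list alone, was Mrpl9, which fell. As another test, limma's fry for a shift in 1 direction called 0 of 22 lists, with 3 at an unadjusted p under 0.05. Its test for changes in either direction gave an unadjusted p = 0.0133 for the respiratory chain and 0.00399 for the mitochondrial mRNAs. That test gave 0.0823 for the cytosolic ribosomal, 0.0232 for the mitochondrial ribosomal and 0.00779 for the proteasome list. In 100 simulations of unchanged groups that kept the correlation between genes, a mean of 2.52 lists were called in aged against young, and 19 of the 100 gave at least the 5 observed. The directions of the list medians were kept under all 3 scalings. The scalings could hardly change them, since the respiratory chain median, for example, moved only between 0.644 and 0.666. The fixed lists held 76 respiratory chain, 79 cytosolic ribosomal, 38 proteasome and 76 mitochondrial ribosomal genes. Those not tested were below the filter or not in the deposited data, so each median describes only part of its list.

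Aged replicate 2 had the highest sum in each of these 4 lists. It held 1090 FPKM over the respiratory chain genes against 513 to 711 in the other 8 libraries, and 854 over cytosolic ribosomal genes. Aged replicates 1 and 3, at 478 and 434 FPKM, lay below all 3 young libraries (499 to 588) in the latter, and the NMN libraries had 425 to 661. Over mitochondrial ribosomal genes it held 622 against 429 to 598, and over proteasome genes 1170 against 770 to 1130. Without it the respiratory chain list kept its call (adjusted p = 0.00302), and the cytosolic ribosomal (0.274), mitochondrial ribosomal (0.514) and proteasome lists (0.358) lost theirs. In that fit 40 respiratory chain and 30 cytosolic ribosomal genes passed the filter, against 44 and 33 with all libraries. The mitochondrial ribosomal list was also lost without young replicate 2 (0.0554), young replicate 3 (0.245) or NMN replicate 3 (0.0520), and the proteasome list without young replicate 3 (0.210). With each library's length trend removed the mitochondrial ribosomal and proteasome lists had adjusted p = 0.236 and 0.180, and with values as deposited the mitochondrial ribosomal list had 0.0529. At a minimum of 10 FPKM the respiratory chain (adjusted p = 0.110), cytosolic ribosomal (0.313), mitochondrial ribosomal (0.817) and proteasome lists (0.110) were not called, and of the 5 lists only the mitochondrial mRNAs were.

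Among meiotic, cytoskeletal and egg coat genes, single members moved without a shift of their lists in 1 direction (camera adjusted p from 0.166 to 0.753). For changes in either direction, limma's fry gave an unadjusted p = 1.65e-05 for the egg coat and 6.85e-05 for the cohesin list. It gave 0.000607 for the kinetochore, 0.00659 for the actin, 0.0157 for the spindle and 0.0729 for the meiotic arrest list. Cdca5, which stabilises sister chromatid cohesion, fell from 83.4 ± 2.84 to 45.4 ± 10.3 FPKM, and Hormad1, a protein of the meiotic chromosome axis, rose from 15.2 ± 3.88 to 41.6 ± 6.38 FPKM (limma adjusted p = 0.0430 and 0.0431). Mis18a, a centromere factor, rose from 2.69 ± 0.57 to 8.03 ± 1.20 FPKM (adjusted p = 0.0117), and Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, from 31.4 ± 4.77 to 84.8 ± 16.0 FPKM (adjusted p = 0.0270). Tuba1c, Nusap1 and Tubb5 of the spindle list and Tpm4, Cdc42 and Cfl1 of the actin list rose (log2 changes from 1.03 to 1.57, adjusted p from 0.0209 to 0.0473). Zp3, a zona pellucida protein that binds sperm, rose from 116 ± 11.03 to 258 ± 71.2 FPKM (adjusted p = 0.0371). Adjusted over the list alone, 3 cohesin and meiotic chromosome genes rose and 1 fell, and 1 kinetochore, 5 spindle and 5 actin genes rose while 1 actin gene fell. Likewise, 2 meiotic arrest genes rose and 1 fell, and 2 egg coat genes rose and 1 (Vamp3) fell. Apart from Vamp3, none of these single-gene calls held when each of the 9 libraries was left out in turn, and the highest adjusted p was 0.199, for Cfl1 without young replicate 3.

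The genes that the NMN question points to did not pass the test in aged against young oocytes. The NAD metabolism and sirtuin list held 35 fixed genes, and of the 15 tested no member passed (camera adjusted p = 0.753). Nampt, the rate-limiting enzyme of NAD salvage, was at 1.34 ± 0.40 FPKM in young and 1.049 ± 0.383 in aged. Nmnat1 was at 1.53 ± 0.32 and 0.89 ± 0.42, and Sirt1 at 2.60 ± 0.95 and 3.96 ± 1.54 (limma adjusted p from 0.309 to 0.696). At such low values the log2(FPKM + 1) scale understates changes, so these genes could differ without a call. No antioxidant gene passed of the 25 tested from a fixed list of 49 (camera adjusted p = 0.636). Sod2 was at 14.2 ± 1.33 and 13.7 ± 1.053 FPKM, Prdx1 at 719 ± 98.2 and 807 ± 82.9 and Sod1, also low, at 1.47 ± 0.84 and 2.96 ± 1.18. Gpx4, Sirt2, Sirt3 and Rec8 stayed below the filter and were not tested. Other fixed genes without a call (limma adjusted p from 0.183 to 0.881) were Astl (162 ± 10.3 and 229 ± 94.7), the sperm receptor Izumo1r (33.8 ± 3.50 and 39.8 ± 9.65), Zp1 (89.5 ± 11.5 and 167 ± 99.9), Zp2 (37.5 ± 7.41 and 104 ± 74.4), Bub1b (378 ± 54.3 and 399 ± 69.5) and Dnmt1 (142 ± 5.88 and 186 ± 39.9 FPKM). The wide spread of Zp1 and Zp2 came with 262 and 186 FPKM in aged replicate 2. Among the remaining lists, with 0 limma calls over all genes, 3 chromatin genes rose and 1 fell and 2 chaperone genes rose when adjusted over the list alone.

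In NMN against aged oocytes, 5 genes met the naming rule, and all 5 moved back toward or past the young level. Vamp3 rose from 8.06 ± 1.11 to 33.9 ± 2.35 FPKM (log2 change 1.95 ± 0.17 SE, limma adjusted p = 0.00190, n = 3), against 28.1 ± 2.99 in young oocytes. Bst2 rose from 5.27 ± 1.68 to 28.9 ± 13.2 FPKM (2.17 ± 0.35, adjusted p = 0.0433; young 17.5 ± 1.77) and Zfp961 from 12.5 ± 2.502 to 39.2 ± 5.10 (1.58 ± 0.22, adjusted p = 0.0177; young 55.5 ± 12.4). Kpna2, an adaptor of nuclear import, fell from 84.2 ± 11.8 to 36.2 ± 1.97 FPKM (-1.19 ± 0.17, adjusted p = 0.0165; young 32.6 ± 2.31), and Dppa1 from 21.5 ± 4.70 to 7.98 ± 1.37 (-1.31 ± 0.21, adjusted p = 0.0409; young 9.15 ± 1.14). Plek, a substrate of protein kinase C that was chosen after its values were seen, fell from 5.92 ± 0.39 to 1.02 ± 0.18 FPKM and lay below the young level of 4.49 ± 0.22. Leaving out 1 library ended the calls of Bst2 (adjusted p up to 0.173, without NMN replicate 1), Zfp961 (0.0920) and Dppa1 (0.188), both without NMN replicate 3, and Kpna2 (0.105, without aged replicate 3). Dppa1 missed the threshold whichever of the 9 libraries was left out.

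**Figure D2:**
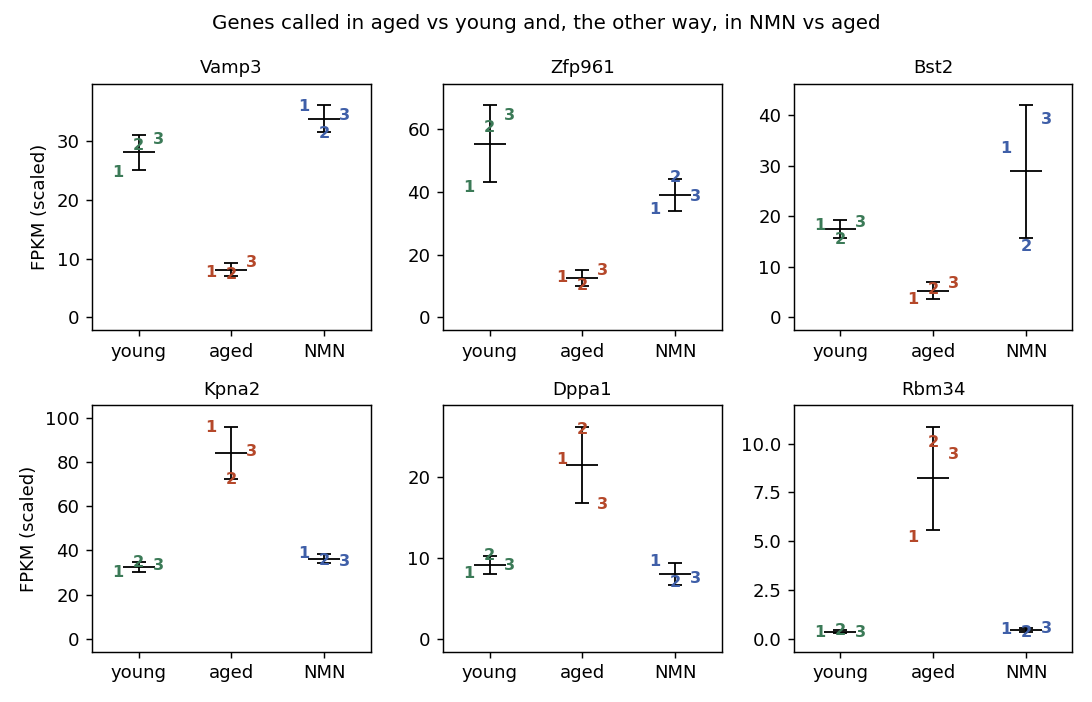
FPKM after scaling of 6 genes in young, aged and NMN libraries, with digits for the replicates and bars for mean ± SD (n = 3). Vamp3, Zfp961 and Bst2 were lower and Kpna2, Dppa1 and Rbm34 higher in the aged group than in the other 2 groups.

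In all, 20 of 9168 genes were called in NMN against aged oocytes, 11 higher and 9 lower (limma), with 1007 at an unadjusted p under 0.05 against 458.4 by chance. Other settings gave from 4 calls at a minimum of 10 FPKM to 147 with library quality weights. The groups did not overlap for 1442 genes (15.7%, with 10% by chance). The count was 8 without aged replicate 1, 5 without aged replicate 3, 11 without NMN replicate 1 and 26 without aged replicate 2. Of the 13 calls named for this comparison, 11 remained without each young replicate and 9, 10 and 9 without NMN replicates 1 to 3. Without an aged replicate, Rbm34, Gm13103, Gm13089 and Gm11380 fell below the filter and were not tested, and of the other 9 calls 5, 7 and 3 remained without aged replicates 1 to 3. These 4 genes were called in all 6 fits that tested them. Of all 20 calls, 15 were still tested without an aged replicate and 17 without an NMN replicate. The calls of Vamp3, Uba6 and E330012B07Rik held without any 1 library. Of the 20 genes, 5 were not called in aged against young: Plek, Gm21411, Gm47871, Gm16380 and H2-T-ps, the last 4 also chosen after their values were seen.

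In NMN against aged oocytes 3 lists were called, and 49 of the 100 simulations of unchanged groups that kept the correlation between genes gave at least 3. The respiratory chain list fell with a median of -0.32 and the cytosolic ribosomal list with a median of -0.37 (camera adjusted p = 0.0106 for both), and the mitochondrially encoded mRNAs rose with a median of 0.39 (adjusted p = 0.0147). With an estimated correlation the first and last had an adjusted p = 0.786 each and the ribosomal list had an adjusted p = 0.836. No member of these 3 lists passed the limma test over all genes, and adjusted over the list alone 1 mitochondrial mRNA rose, mt-Atp6, from 29.8 ± 10.6 to 70.1 ± 5.52 FPKM. The sum of mitochondrial mRNAs was 4085 ± 415 FPKM in NMN libraries (exact permutation p = 0.4 against aged). Without aged replicate 2, which had the highest sums over respiratory chain and ribosomal genes, both of those lists lost their call (adjusted p = 0.786 for each), and the mitochondrial mRNA list had a median of 0.82 (adjusted p = 6.56e-08). The first 2 were also lost without NMN replicate 2 (0.169 and 0.394), and the mitochondrial mRNAs without aged replicate 1 (0.153), aged replicate 3 (0.402) or NMN replicate 2 (0.125). With each library's length trend removed the first 2 had an adjusted p = 0.119 each, and at a minimum of 10 FPKM the respiratory chain, ribosomal and mitochondrial mRNA lists had adjusted p = 0.475, 0.745 and 0.0820. All 3 had been called in the opposite direction in aged against young, which uses the same aged libraries. In the same 100 simulations a mean of 1.11 and at most 5 lists were called in both comparisons in opposite directions, and 22 of the 100 gave at least the 3 observed. The other 19 lists were not called, with adjusted p from 0.0729, and the 1 member past the test in any list was Vamp3, while adjusted over the list alone 2 kinetochore genes (Mis18a and Ndc80) and 2 actin genes (Cdc42 and Tpm4) fell.

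**Figure D3:**
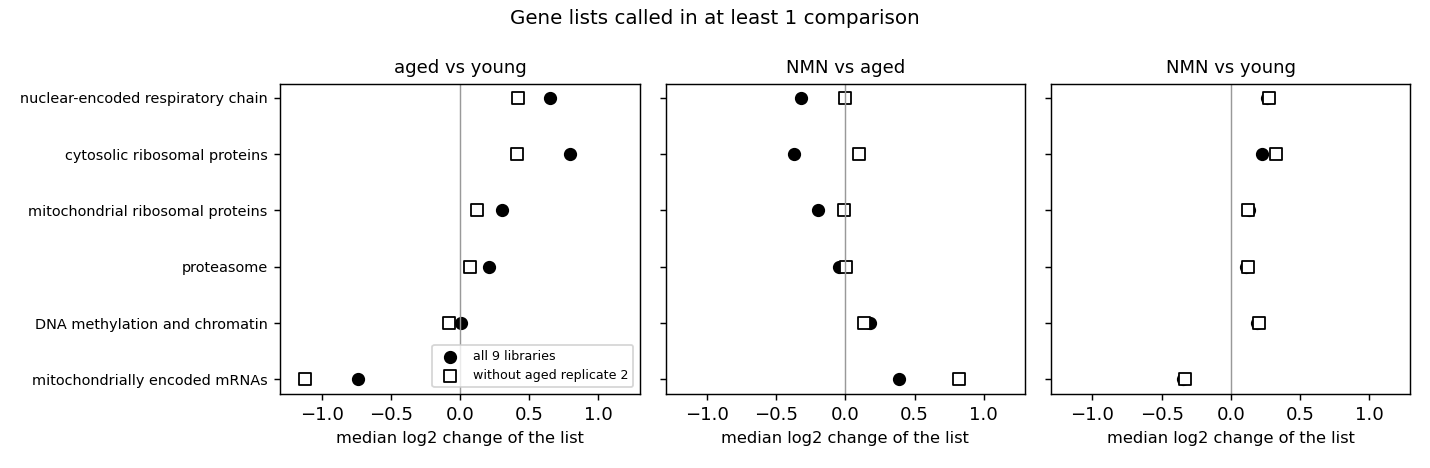
Median log2 change over the tested members of 6 gene lists in each comparison, from all 9 libraries (filled circles) and without aged replicate 2 (open squares). In aged against young the mitochondrial mRNAs moved from -0.73 to -1.12 and the respiratory chain from 0.65 to 0.42 when that library was left out.

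Of the genes called in aged against young, 15 were also called in NMN against aged, all with the opposite sign, 7 higher in aged and 8 lower. The 10 most firmly called were Vamp3, Kpna2, Uba6, an activating enzyme of ubiquitin transfer, Rbm34, an RNA-binding protein, Arntl2, a clock transcription factor, E330012B07Rik, Gm13103, Gm13089, Gm44609 and Gm11380. Uba6 was at 3.14 ± 0.60 FPKM in young, 0.25 ± 0.04 in aged and 2.90 ± 0.35 in NMN. Arntl2 was at 4.34 ± 0.61, 0.17 ± 0.04 and 4.07 ± 1.78 FPKM. Rbm34 went from 0.36 ± 0.08 to 8.23 ± 2.64 and 0.45 ± 0.11. Gm44609 was listed at 0 in the 3 aged libraries and at 29.3 to 45.8 FPKM in young ones. Of the 201 calls, 194 (96.5%) had an NMN value shifted toward or past young, 182 of them between the aged and young means and 12 beyond young, with a median of 0.604 of the difference recovered. Because the aged libraries enter both comparisons, unchanged groups also give opposite moves. In 100 simulations of unchanged groups with independent genes, the 201 genes with the smallest p in aged against young gave a mean of 94.9% opposite (90.55 to 98.0%) and a mean recovery of 0.774 (0.700 to 0.863). In the 100 simulations that kept the correlation between genes the means were 82.2% (2.49 to 100%) and 0.477 (-1.33 to 2.94), and 46 of them gave at least the observed percentage. Neither the observed percentage nor the recovery lay above the simulated range, though a percentage cannot exceed a range that reaches 100%. The simulations that kept the correlation between genes gave every group the same spread. They therefore leave out the wider spread of the aged libraries, which enter both comparisons, and their means are no firm baseline for the observed values. The recovery of 0.604 lay below the range of the simulations with independent genes and within that of the other simulations. For the 15 genes called in both with opposite signs, the first simulations gave a mean of 0.23 and at most 2, the second gave 0 in each, and independent lists of these sizes would share 0.123 and 0.0912 genes in the 2 directions. With all groups unchanged, counts near 0 were fixed in advance, and independent lists leave out the shared libraries. None of these values shows how many of the 201 calls the shared aged libraries alone would turn opposite.

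Across all tested genes, 73.0% had opposite signs against 71.2% in the simulations with independent genes. The correlation of the fold changes across genes was -0.678 (simulated -0.665), and the covariance was -0.140 against -0.0725, a difference of -0.0679. In the simulations that kept the correlation between genes the means were 66.4% (26.9 to 90.9%), -0.456 (-0.953 to 0.690) and -0.0499 (-0.305 to 0.0313), and 7 of the 100 had a covariance as low as the observed one. All 3 observed values thus lay within the range of the simulations that kept the correlation between genes. Those simulations gave every group the same spread, so how rare the observed covariance is cannot be read from them. In those with independent genes the simulated covariance had an SD of 0.002485, and the observed -0.140 lay far below its mean of -0.0725. With 3 aged libraries no split into parts of at least 2 was possible, so part of the 15 opposite calls may come from the shared libraries. The count of 15 was 7 without aged replicate 1, 3 without aged replicate 3, 9 without NMN replicate 3 and 19 without aged replicate 2. Part of the drop came from the filter, since 5 of the 15 were not tested without an aged replicate, and of the other 10 genes 5, 7 and 3 were still called in both without aged replicates 1 to 3. Other settings gave from 4 genes at a minimum of 10 FPKM to 113 with library quality weights.

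NMN and young oocytes differed in 3 genes (limma), of 755 with an unadjusted p under 0.05 against 458.4 by chance. Other settings gave from 0 calls with no low-value filter (1260 genes at an unadjusted p under 0.05) to 73 with library quality weights, and the 6 libraries of both groups alone gave 16. Tmed2 was at 107 ± 20.9 FPKM in NMN and 11.1 ± 2.03 in young oocytes (log2 change 3.15 ± 0.26 SE, adjusted p = 0.00220, n = 3), a level near that of the aged group. Ddx55, an RNA helicase, rose from 1.70 ± 0.15 to 6.98 ± 1.54 FPKM (adjusted p = 0.0357), and Plek fell by 1.44 on the log2 scale (adjusted p = 0.0226). Ddx55 and Plek were chosen after their values were seen. With the replicate number as a block, Tmed2 was the single call (adjusted p = 0.0455). The groups did not overlap for 1524 genes (16.6%, with 10% by chance). Tmed2 was the single call without any 1 of the young replicates, aged replicate 1 or 3, or NMN replicate 1, and the count was 14 without aged replicate 2 and 13 without NMN replicate 3. Nampt was at 0.73 ± 0.24, Sirt1 at 4.24 ± 0.97 and Nmnat1 at 1.64 ± 0.27 FPKM in NMN oocytes and passed the limma test neither against young nor against aged (adjusted p from 0.430 to 0.941).

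The mitochondrially encoded mRNAs were lower in NMN than in young oocytes as a list, with a median of -0.34 (camera adjusted p = 0.00397), and respiratory chain genes were higher, with a median of 0.26 (adjusted p = 0.00397). DNA methylation and chromatin genes (median 0.19, adjusted p = 0.00775), proteasome genes (0.11, 0.0151) and cytosolic ribosomal genes (0.22, 0.0478) were higher too. With an estimated correlation each of these 5 lists had an adjusted p = 0.896, and 16 of the 100 simulations that kept the correlation between genes gave at least 5 lists. No member of any of the 22 lists passed the limma test over all genes, and adjusted over the list alone 1 mitochondrial mRNA fell, mt-Nd1 (782 ± 115 FPKM in NMN), and 1 meiotic chromosome gene rose, Hormad1 (15.2 ± 3.88 in young and 44.2 ± 15.7 FPKM in NMN). NMN replicate 1, next to aged replicate 2 on the first component, had the highest sums of its group. They were 711 FPKM over respiratory chain genes against 578 and 599, 661 against 425 and 535 over cytosolic ribosomal genes and 1130 against 861 and 883 over proteasome genes. Without it, the respiratory chain (adjusted p = 0.192), cytosolic ribosomal (0.738) and proteasome lists (0.340) lost their call. Calls were also lost without young replicate 2 for the chromatin (0.109) and cytosolic ribosomal lists (0.112), without young replicate 3 for the cytosolic ribosomal (0.306) and proteasome lists (0.232), and without NMN replicate 3 for the cytosolic ribosomal list (0.1). At a minimum of 10 FPKM the respiratory chain and cytosolic ribosomal lists had adjusted p = 0.180 and 0.298. The cytosolic ribosomal list had an adjusted p = 0.0630 with the replicate number as a block and 0.103 with values as deposited.

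Markers of any 1 type of other cells held at most 0.0628% of the summed FPKM of a group. This share does not bound the RNA of such cells. Serpine2 made up 74.6 to 89.2% of the cumulus, erythrocyte, immune and stroma marker sum in every library. Aged replicate 2, with cumulus markers of its own, had the lowest Serpine2, at 128 FPKM. Cumulus and granulosa markers summed to 172 ± 12.7 FPKM in young, 190 ± 30.8 in aged and 194 ± 23.4 in NMN libraries (exact permutation p = 0.6 for aged against young), mainly from Serpine2. Of their 20 markers in the table, 4 passed the filter. Immune markers summed to 8.16 ± 2.49, 5.05 ± 0.88 and 9.52 ± 2.91 FPKM in the same order. Stroma and endothelium markers summed to 9.18 ± 1.63, 10.04 ± 2.39 and 9.27 ± 2.39 FPKM, male germ cell markers to 1.78 ± 0.36, 1.89 ± 1.14 and 1.60 ± 0.40, and the erythrocyte marker Alas2 was at 0.063 ± 0.038, 0.16 ± 0.18 and 0.017 ± 0.029. Oocyte markers summed to 7716 ± 596, 9603 ± 611 and 8580 ± 779 FPKM. Immediate early genes summed to 66.2 ± 7.72, 112 ± 20.2 and 70.6 ± 10.3 FPKM, and early embryonic transcripts to 61.1 ± 14.8, 135 ± 71.2 and 67.9 ± 28.3, mainly from Tcstv1, with 214 in aged replicate 2. The immediate early sums came mainly from Dusp1 except in aged replicate 2, where Dusp1 was at 34.0 FPKM, below the 43.75 to 60.3 of the young libraries, and Ier3 at 34.9. The immune, oocyte, immediate early and early embryonic sums did not overlap between aged and young libraries, where the exact permutation test gave its smallest p of 0.1, and the immune and immediate early sums did not overlap between NMN and aged libraries (p = 0.1).

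**Figure D4:**
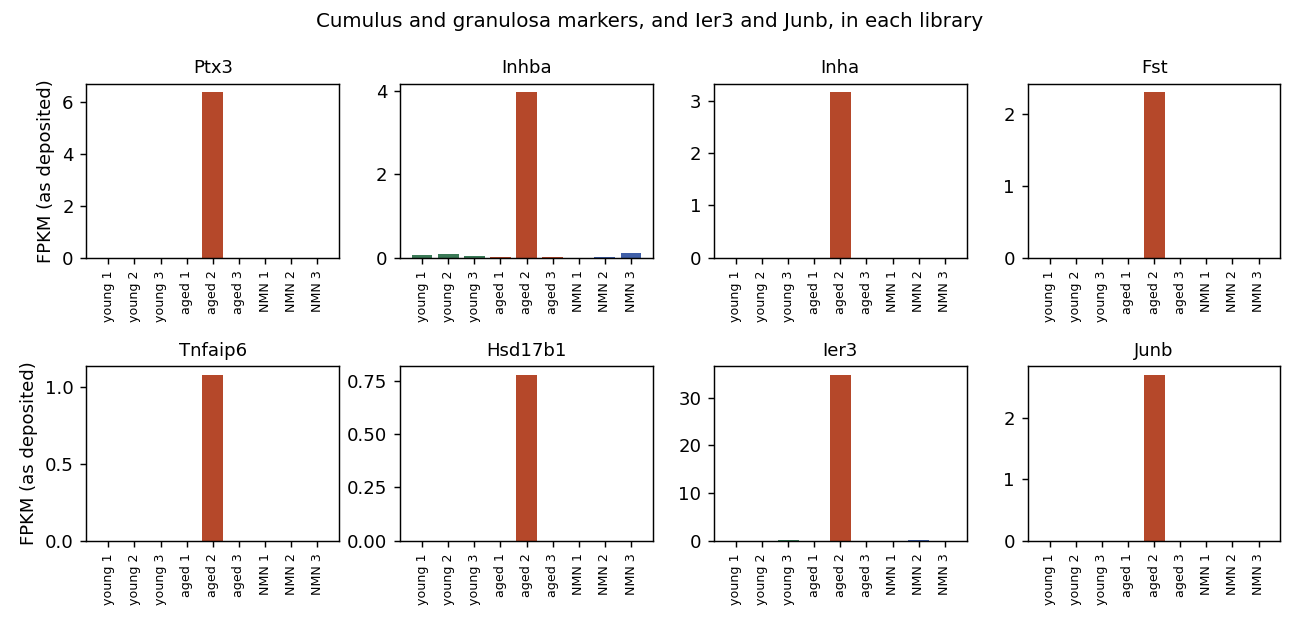
FPKM as deposited of 6 cumulus and granulosa markers and of the immediate early genes Ier3 and Junb, 1 bar per library. Aged replicate 2 held 6.37 FPKM of Ptx3 and 34.9 of Ier3, and the other 8 libraries were at or near 0 for all 8 genes.

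Tmed2 and Ddx55 lie beside each other, within a stretch of 20 neighbouring tested genes that held 8 of the calls in aged against young. Tmed2, Ddx55, Mphosph9, Dnah10 and Scarb1 were higher in the aged group, and Rilpl1, Vps37b and Pitpnm2 lower. Scarb1, a receptor for high-density lipoprotein, was at 1.81 to 2.18 FPKM in young and 5.12 to 9.86 in aged libraries, and Rilpl1 at 2.03 to 3.42 and 0 to 0.21. All 8 had the same sign in NMN against young, as 189 of the 201 called genes did, since both comparisons use the young libraries. Each of the 8 had an unadjusted p under 0.05 there, as did 101 of the 201 with the same sign, and 2 were called. The labels do not say whether the aged and NMN mice came from another batch of animals than the young. Apart from Tmed2 and Vps37b, these genes were chosen after their values were seen.

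**Figure D5:**
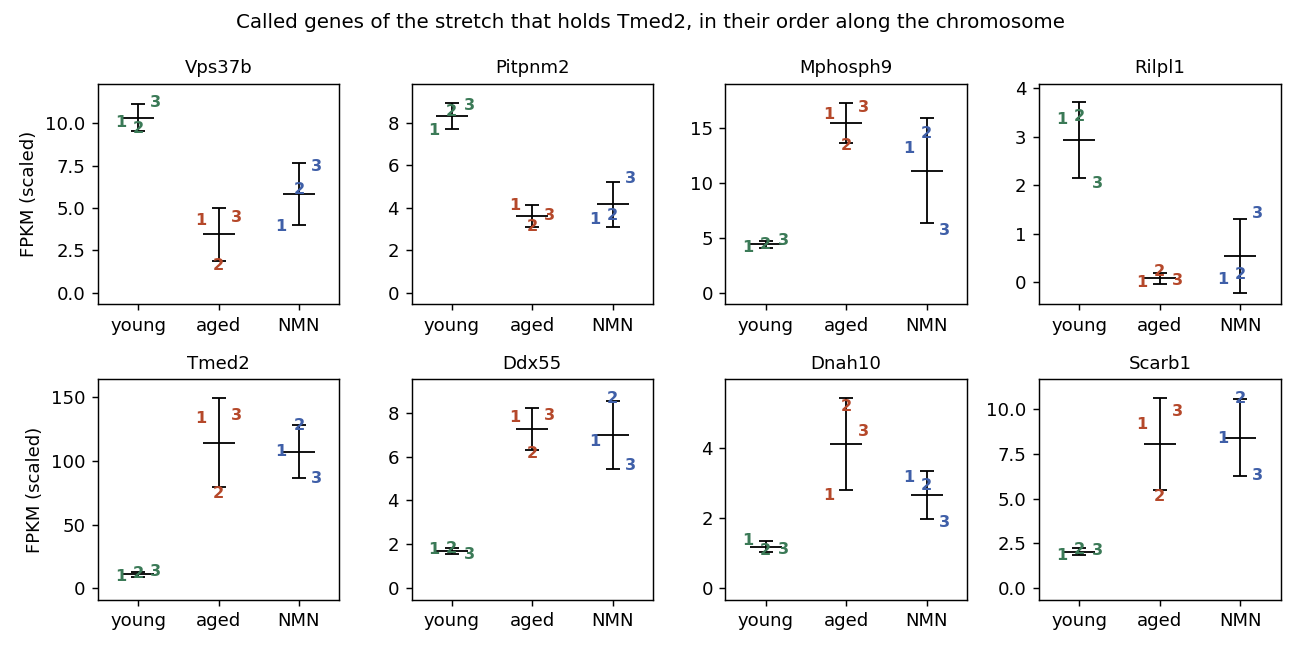
FPKM after scaling of the 8 called genes in the stretch that holds Tmed2, in their order along the chromosome, with digits for the replicates and bars for mean ± SD (n = 3). The NMN libraries lay on the aged side of the young ones for all 8, with Tmed2 at 86.4 to 128 FPKM in NMN and 8.90 to 12.8 in young libraries.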

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

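The settings with pseudocounts of 0.1 and 5, with each library's length trend removed (alone or with the replicate block), with a detection limit of 1 FPKM, and the list tests without aged replicate 2 were chosen after the data were seen. For the 59 named calls, 1018 values under other settings gave 694 that stayed past the limma threshold, 324 that missed it with the same direction, and 0 that changed direction. The groups did not overlap for any called gene, so these settings could hardly change a direction. Counts of calls for aged vs young, NMN vs aged, NMN vs young and both with opposite signs were 201, 20, 3 and 15. With median-ratio factors they were 199, 20, 3 and 15, with values as deposited 162, 18, 3 and 13, and with a log2 change of at least 1 they were 176, 20, 3 and 15. With no low-value filter, where 22526 genes were tested, they were 31, 9, 0 and 8 (limma, with 1260 genes at an unadjusted p under 0.05 in NMN vs young). At a minimum of 10 FPKM, where 3540 genes were tested, they were 93, 4, 1 and 4. Library quality weights gave 881, 147, 73 and 113. The cause was not tested, and such weights are themselves estimated from these 9 libraries. A pseudocount of 0.1 gave 13 calls in NMN vs aged and 5 in NMN vs young, and a pseudocount of 5 gave 12 and 1, with 8 genes called in opposite directions. The cause was not tested. With each library's length trend removed there were 207, 21, 8 and 17, for causes not tested. From the 6 libraries of the groups compared alone there were 129, 7 and 16 calls. Leaving out 1 library gave 29 to 211, 5 to 26, 1 to 14 and 3 to 19, and the percent of aged vs young calls with an opposite NMN move, 96.52 with all libraries, lay between 86.54 and 100.

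The samples share replicate numbers. By the correlation of their deviations, libraries of the same number were treated as pairs in NMN vs young and not in the other comparisons. That choice was read from these same data. Of the 9 libraries, 4 correlated best with their own number. With the replicate block the counts were 75, 15, 1 and 11, and 100% of the 75 had an opposite NMN move. The block moved the number of called lists to 5, 4 and 4, adding 1 call in NMN vs aged. In NMN vs young it ended the calls of Ddx55, Plek and the cytosolic ribosomal list (adjusted p = 0.0630) and changed no other call. With the length trend removed in the same fit there were 1 call and 5 lists in NMN vs young, the ribosomal list at an adjusted p = 0.0495.

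Of the 22 gene lists, camera with the preset correlation called 5, 3 and 5. With an estimated correlation it called 0, 0 and 0 (0 in each at an unadjusted p under 0.05). For a shift in 1 direction fry called 0, 0 and 0 (3, 2 and 0 at an unadjusted p under 0.05). Its test for changes in either direction had a lowest unadjusted p of 1.65e-05, 7.23e-06 and 0.0367. These belonged to the egg coat list in aged vs young and in NMN vs aged, and to the cohesin list in NMN vs young. With the length trend removed there were 3, 1 and 5, without mitochondrial ribosomal and proteasome genes in aged vs young and respiratory chain and cytosolic ribosomal genes in NMN vs aged. At a minimum of 10 FPKM, which leaves fewer members per list, there were 1, 1 and 3. The 1 in NMN vs aged was none of the 3 called with all tested genes. Leaving out 1 library gave 2 to 6, 0 to 4 and 2 to 6. The difference in the number of genes detected between NMN and young libraries was -139.7 for genes above 0 and 110.3 for genes at 1 FPKM or more.

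Direction changed only in comparisons in which the gene was not called, and the causes were not tested. With values as deposited the log2 change of Astl in NMN vs aged was 0.0286 and that of Zp1 in NMN vs young 0.0260. Astl was at 0.0357 with no filter and at 0.0171 with the length trend removed, where Sod2 in aged vs young was at 0.00306. With quality weights Bub1b in NMN vs aged was at -0.0428, Zp1 in NMN vs young at 0.13 and Izumo1r in NMN vs young at -0.00621. Leaving out 1 library gave, in aged vs young, -0.12 to 0.0230 for Sod2 and -0.0429 to 0.19 for Bub1b. In NMN vs aged it gave -0.32 to 0.28 for Astl, -0.0805 to 0.36 for Sirt1, -0.32 to 0.0256 for Izumo1r, -0.18 to 0.11 for Dnmt1, -0.0156 to 0.20 for Bub1b and -0.62 to 0.0233 for Sod1. In NMN vs young it gave -0.0599 to 0.0976 for Izumo1r, -0.0469 to 0.16 for Nmnat1, -0.26 to 0.15 for Zp1, -0.39 to 0.0404 for Arntl2, -1.24 to 0.00866 for Gm44609 and -0.0141 to 0.0474 for Gm13103. A Wald count test and thinning to equal depth need read counts and were not run. Depth limits what can be seen below 0.0779 to 0.0921 FPKM for a transcript of 2 kb.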

Other observations

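The tests of sequencing depth, of RNA from cumulus cells, of transcripts of at most 1000 nt, of shared haplotypes among neighbouring calls, of the stretch, of the mitochondrial rRNAs and of nuclear genes of like level were chosen only after the result was seen. Among the genes called in aged against young and, with the opposite sign, in NMN against aged were also Nptx2, a pentraxin, and Pls3, an actin-bundling protein, chosen after their values were seen. Nptx2 was at 3.93 FPKM in young, 1.31 in aged and 6.46 in NMN oocytes (log2 change -1.10 in aged against young and 1.71 in NMN against aged, limma adjusted p = 0.0390 and 0.0134). Pls3 was at 0.28, 2.81 and 0.12 FPKM (1.52 and -1.71, adjusted p = 0.0218 and 0.0331). The 3 against 3 libraries of a comparison allow 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many calls as observed (201, 20 and 3, limma), and the highest other gave 0. In NMN against young, where libraries of the same number were treated as pairs, 4 splits parted all 3 pairs. The 3 of these other than the real one gave 0 calls.

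Aged replicate 2 stood apart from the other libraries, with 35 genes over 2 times the level of every other library (at most 1 elsewhere) and 57 genes under 50% of every other library (at most 11 elsewhere). Shallower sequencing is argued against by NMN replicate 3, with 16.54 M reads against 16.28 M and a first component of -5.17, and a linear trend with transcript length and GC content by its share of 1.12% of the variance, though no linear trend can follow medians of 0.166, 0.44, 0.115, -0.144 and 0.0636 on the log2 scale from the shortest to the longest of 5 length classes (NMN replicate 1 had 0.352 in the second). RNA of cumulus cells in that library is a candidate, since it had 5 of 20 cumulus markers of its own (0 in every other library). One high gene, Spp1, was at 442 FPKM there and listed at 0 elsewhere. None of these 5 markers is among the 35 high genes, so they do not show the origin of the high genes. A preference for short transcripts is a candidate too. Of the high genes, 62.9% have at most 1000 nt against 8.48% of all genes of that level (Fisher exact p = 6.46e-16). Added RNA of cumulus cells is argued against as the source of the 57 low genes, since it would lower the other transcripts alike and the remaining genes of that level had a median ratio of 0.998 to the other libraries, and oocyte genes such as Zp2, Omt2b and Tcl1b5 are among the high ones. RNA of other cells for the library as a whole stays open, since its marker sum was 0.723 times the highest of the others but 74.6 to 89.2% of that sum was Serpine2 in every library, and no biological explanation was tested.

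The 8 calls around Tmed2 within 20 neighbouring genes exceeded the fullest stretch of every 1 of 10000 random gene sets (median 4, highest 7, permutation p = 1e-04, the smallest they can give), and 7 of them were called without aged replicate 2. Reads shared between overlapping genes are argued against, since 0% of these 8 genes overlapped another of them. A candidate explanation is that the mice within a group of this outbred strain shared a haplotype there, which the aged and NMN mice may have had in common if they came from another batch of animals than the young, a point the labels leave open. Over the whole genome 10 called genes lay beside a gene called the same way (random mean 4.53, permutation p = 0.072), with 0% of the 5 pairs overlapping, so that whether haplotypes account for other calls stays open. Age itself, which the design names, stays open for this stretch too and was not tested apart from the donors, so that Tmed2 and the other 7 genes may differ for either reason.

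Mitochondrially encoded mRNAs were lower in the aged group. The highest camera p under 3 scalings, 2.57e-06, decides nothing on the scaling between libraries, which moved the list's median by only 0.0234, but a scaling that shifts genes of their expression level is argued against by the 100 nuclear genes nearest in level to each mRNA, with a median as deposited of -0.0385 against -0.718 for the list (-0.0184 over all 6085 nuclear genes within its range). With an estimated correlation of 0.676 between these genes camera gave p = 0.105 (adjusted p = 0.803, and 0.0556 without aged replicate 2), so that a shift of the list beyond the spread of these libraries stays open. A lower yield of all mitochondrial transcripts cannot be told apart from a change of the mRNAs, since the median log2 difference was -0.661 for mt-Rnr2 (lower in 6 of 9 pairs of libraries) and 0.03 for mt-Rnr1 (lower in 4 of 9), and mt-Rnr1 was at 735 FPKM in aged replicate 2. Age, and the poly(A) tails on which priming by oligo(dT) depends, stay open and were not tested.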
